A study of Mus musculus with 27 samples.

How the data were processed

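Polyadenylated RNA from mouse kidneys was sequenced as stranded mRNA libraries from total RNA, per the labels, in 2 kidney experiments with 9 and 12 libraries. The replicates were separate animals per the labels, all male, and no library was pooled. Another 6 samples of the series were livers, for which no values were at hand, so they were not analysed here. Of the sample columns in the deposited tables, 0 could not be matched to a label.

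The deposited tables gave counts per gene symbol and, separately, TPM, which scales counts by transcript length and library total, for 24475 symbols in each experiment. The deposited count values were whole numbers with a different total in each library, so they were taken as raw counts. The TPM values, computed by the authors, had the same sum in each library. Per the submitters' processing notes, base calling used CASAVA 1.8.2 and reads were checked with FastQC and assigned to the mouse build GRCm38. The aligner, the counting program and the annotation were not given in the sources used here. Chromosome positions were taken from a GENCODE annotation of GRCm38, which may not be the annotation the authors used.

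Total counts ran from 10323922 to 13566892 in the WT and from 10330981 to 14560177 in the huC3 libraries of experiment 2. In experiment 3 they ran from 13224153 to 15994546 in WT, from 11685495 to 16298253 with control antibody and from 12604611 to 23351090 with anti-C5. Floors cover counting error only, and reads without molecular identifiers are not independent molecules. The SE of a log2 fold change was derived from the edgeR test, as its absolute value divided by the square root of the quasi-likelihood F. The 95% interval was built from that SE with a t quantile and covers variation between animals. The mitochondrial gene COX1 took the most counts in every library. The 10 most abundant genes took 22.5% ± 0.386 (SD, n = 3) of counts in WT and 16.8% ± 1.87 (SD, n = 6) in huC3 kidneys of experiment 2. In experiment 3 they took 20.0% ± 3.76 (SD, n = 5) in WT, 18.8% ± 1.28 (SD, n = 3) with control antibody and 23.2% ± 2.61 (SD, n = 4) with anti-C5. Scaling factors from the trimmed mean of M-values (TMM) ran from 0.851 to 0.868 in WT and from 0.975 to 1.25 in huC3 libraries of experiment 2. The ranges in experiment 3 were 0.896 to 1.03 in WT, 1.08 to 1.19 with control antibody and 0.896 to 0.971 with anti-C5. Within groups, pairs of libraries differed by a chi-square per gene of at least 7.39, over genes with at least 20 counts in the pair, where repeats of 1 library would give about 1.

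Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group, estimated dispersions and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over the genes tested. Genes with an adjusted p under 0.05 are called higher or lower. Experiment 2 was fitted alone, and the 3 groups of experiment 3 were fitted together. The 4 comparisons were huC3 against WT in experiment 2 and, in experiment 3, huC3 with control antibody against WT, anti-C5 against control antibody, and anti-C5 against WT. A fit of both experiments tested the interaction of experiment and genotype. Log2 fold changes used edgeR's prior count of 0.125. Levels are CPM, counts scaled by TMM to 1000000 per library, as mean and SD over libraries. A fold against a group without any count was bounded with 3 counts over that group's libraries. On simulated counts with the same group sizes, edgeR recovered 62.7% of the genes changed 2-fold in the design of experiment 2, and 67.2%, 65.7% and 76.1% in the designs of the 3 contrasts of experiment 3. Of genes changed 1.5-fold it recovered 25.4%, 31.3%, 13.4% and 37.3% in the same order. For the interaction it recovered 46.3% at 2-fold and 4.48% at 1.5-fold. False calls by edgeR were 9 of 131, 5 of 134, 4 of 120 and 6 of 144 in the 4 comparisons. Those by DESeq2 were 38 of 182, 38 of 190, 34 of 170 and 25 of 185.

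Before the data were examined, 28 gene lists were fixed: complement, kidney cell types, leukocytes, injury, matrix, inflammation, metabolism, cell division, stress, and lists for handling and dissection. The adrenal gland list had fewer than 5 measured members and was not tested, which left 27. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, each adjusted by Benjamini-Hochberg over the lists. The comparisons, the tests, the alternatives below and the rule for named genes were fixed at the same time. That rule took C3, Hc, Havcr1, Lcn2, Nphs1, Col1a1, C5ar1 and C3ar1 in every comparison, and a further gene that is not reported here. It then took, per side, the 8 called genes with the largest fold change among those with a mean log2 CPM of at least 1 and with no overlap between the groups. From each list it took up to 4 members with the smallest p, and for results across experiments the 5 genes with the smallest p per side. Predicted genes without a function name are counted but not described. From these a share is named. Named outside the rule, after their values were seen, were Kap and Gpr108 in experiment 2, Kap against WT in experiment 3, and the liver transcripts Alb and Ttr. A list of liver transcripts was written after Alb had been seen, and lists of heat shock chaperones and of cold-inducible RNA-binding proteins after the anti-C5 comparison had been seen. These later lists were adjusted among themselves only, apart from the lists fixed beforehand.

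Alternatives were DESeq2 1.42.0, limma-voom, limma with trend on log2(TPM + 1) or log2(TPM + 0.1) for genes with a TPM of at least 1, and edgeR with median-of-ratios or upper quartile scaling. Others were no filter, a stricter filter of 1 CPM, robust empirical Bayes, a minimum absolute log2 fold change of 1, each replicate left out in turn, and the replicate number as a block. Further ones were the run of submitter numbers as a term, the run of experiment 3 that held the WT animals alone (the WT run), only the 2 compared groups in the fit, age as a covariate in experiment 2, and only the huC3 animals of experiment 2 collected on the day of the WT animals. Chosen after the data were seen were the other run, with huC3 animals only, alone, the gene lists of experiment 2 in the animals collected on the WT day, and the experiment 2 gene sets without heat shock chaperones. A fit of experiment 2 with the earlier-collected huC3 animals as a group of their own was also chosen then. Collection days were computed from date of birth and age, read as days.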

Results

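Kidney gene expression was measured in male mice with a humanized C3 gene (huC3) and in wild-type (WT) mice of a mixed C57BL/6NTac and 129S6/SvEvTac background. C3 is the central protein of the complement cascade, and the series title presents the huC3 mouse as a model of C3 glomerulopathy, a kidney disease with C3 deposits in glomeruli. Total counts per library ran from 10323922 to 23351090. Experiment 2 held kidneys of 3 WT and 6 huC3 mice. Experiment 3 held kidneys of 5 WT mice, of 3 huC3 mice given a control antibody and of 4 huC3 mice given a monoclonal antibody against C5 (anti-C5). C5 is the complement protein cleaved downstream of C3. In experiment 2, huC3 replicates 2, 4 and 5 were collected 27, 23 and 14 days before the WT animals and the other 3 on the same day. In experiment 3 the submitters' sample numbers formed 2 runs. The WT run held all WT animals, 1 control antibody animal and 2 anti-C5 animals. The huC3-only run, collected 7 days earlier, held 2 of each huC3 group and no WT. WT animals were 104 days old in experiment 2, where huC3 animals were 98 to 128 days old and those collected on the WT day 125 to 128. In experiment 3 WT animals were 122 and huC3 animals 112 to 118 days old. No huC3 animal shared a birth date with a WT animal of its experiment, so genotype cannot be separated from birth cohort, nor from age in experiment 3 or on the WT day of experiment 2.

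Mouse C3 transcripts, the product of the replaced gene, were measured first. The gene lies on the minus strand of chromosome 17 from 57203970 to 57228136 (GRCm38). In experiment 2, C3 stood at 20.1 ± 12.1 CPM (SD, n = 3) in WT and 1.42 ± 0.306 CPM (SD, n = 6) in huC3 kidneys. The WT libraries held 32.9, 18.3 and 8.99 CPM and the huC3 libraries 1.08 to 1.95 CPM, from 12 to 26 counts. In experiment 3, the 5 WT libraries held 7.11 to 28.8 CPM and the 4 anti-C5 libraries 0.445 to 1.51 CPM. The library labelled huC3 control antibody replicate 1 held 18.9 CPM (366 counts), within the WT range, while replicates 2 and 3 of that group held 1.57 and 3.31 CPM. Gpr108, which lies 6.5 kb from C3 on the same strand, separated the genotypes in each library, this one included at 80.5 CPM. It stood at 23.5 ± 0.404 (SD, n = 3) and 23.7 ± 2.38 CPM (SD, n = 5) in WT kidneys of experiments 2 and 3. It reached 78.8 ± 10.8 (SD, n = 6) in huC3, 81.4 ± 2.86 (SD, n = 3) with control antibody and 93.1 ± 3.34 CPM (SD, n = 4) with anti-C5. Hc, which encodes mouse C5, had at most 4 counts in any library of experiment 2 and was not tested there. In experiment 3 Hc stood at 0.760 ± 0.635 CPM (SD, n = 5) in WT, 1.30 ± 1.47 (SD, n = 3) with control antibody, drawn from the library labelled huC3 control antibody replicate 1 at 2.99 CPM, and 0.334 ± 0.325 (SD, n = 4) with anti-C5. No Hc difference passed the edgeR test (adjusted p = 0.428 for control antibody against WT, 0.114 for anti-C5 against control antibody and 0.439 for anti-C5 against WT). In WT kidneys of experiment 2 Hc stood at 0.101 CPM. Beside control antibody replicate 1, all 5 WT libraries of experiment 3 and anti-C5 replicate 1 held liver-restricted transcripts (9.89 to 14.9 and 14.8 CPM in sum). Whether Hc counts in these libraries came from kidney was not tested.

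**Figure D1:**
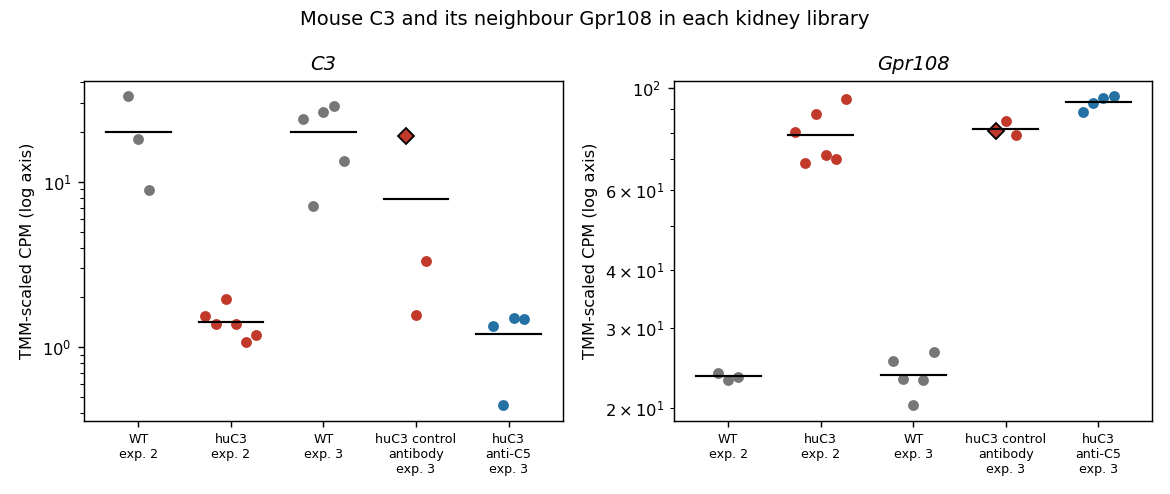
TMM-scaled CPM (log axis) of mouse C3 and of Gpr108 in each of the 21 kidney libraries, with group means as lines and the library labelled huC3 control antibody replicate 1 as a diamond. That library held 18.9 CPM of C3, within the WT range of 7.11 to 28.8 CPM, and 80.5 CPM of Gpr108, far above the WT mean of 23.7 CPM.

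Experiment 2 asked how huC3 kidneys differ from WT kidneys without treatment. Most measured genes of tubular injury, extracellular matrix, macrophages and complement regulation were called higher in huC3 kidneys, 12 of 28 proximal tubule genes were lower, and all 22 of oxidative phosphorylation were lower. As lists these were called by camera at a preset correlation, and none passed with an estimated one (adjusted p = 0.105 to 0.347). Lcn2, a secreted marker of tubular injury, reached 53.0 ± 24.6 CPM (SD, n = 6) against 2.68 ± 1.14 CPM (SD, n = 3) in WT (log2 fold change 4.28 ± 0.59 SE, adjusted p = 0.00261). Col1a1, a chain of type I collagen, reached 109 ± 63.5 CPM (SD, n = 6) against 15.7 ± 4.92 CPM (SD, n = 3), a log2 fold change of 2.80 ± 0.47 (SE, adjusted p = 0.00454). Kap, an abundant androgen-regulated proximal tubule transcript, fell by 2.43 ± 0.57 (SE) on the log2 scale (adjusted p = 0.0139), from 16200 ± 1770 CPM (SD, n = 3) to 3010 ± 2130 CPM (SD, n = 6).

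Of 22 measured tubular injury genes, 20 were called higher and 0 lower in huC3 kidneys (21 and 0 adjusted over the list alone), with a median log2 fold change of 1.98. Camera gave this list an adjusted p of 1.58e-20 (adjusted p = 0.105 with an estimated correlation). Havcr1, the tubular injury receptor, rose by 3.84 ± 0.80 (SE, adjusted p = 0.00929), Vcam1, a leukocyte adhesion molecule, by 3.21 ± 0.31 (SE, adjusted p = 0.00104), and Spp1, osteopontin, by 2.25 ± 0.24 (SE, adjusted p = 0.00124), on the log2 scale. The matrix list had 31 of 33 members higher and 0 lower (31 and 0 adjusted over the list alone). Among them were Col6a1 and Col6a2, chains of collagen VI, at 2.27 and 2.18, and the list's camera adjusted p was 3.2e-23 (adjusted p = 0.144 with an estimated correlation). Macrophage and monocyte genes were higher for 21 of 22 members and lower for 0 (21 and 0 adjusted over the list alone), with a median of 2.34. The macrophage list had a camera adjusted p of 2.67e-20 (adjusted p = 0.144 with an estimated correlation). Itgam, a subunit of the complement receptor for cleaved C3, rose by 3.10 ± 0.34 (SE, adjusted p = 0.00142) on the log2 scale. In the T and NK cell list 8 of 14 were higher (13 adjusted over the list alone; 12 by DESeq2 and 2 by limma-voom), and of 22 cell division genes 17 were higher, Mki67 at 1.94 among them (20 adjusted over the list alone). Their camera adjusted p values were 0.000294 and 9.07e-10 (adjusted p = 0.388 and adjusted p = 0.219 with an estimated correlation).

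Complement regulators and receptors had 12 of 16 members higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 2.03. Their camera adjusted p was 8.59e-10 (adjusted p = 0.105 with an estimated correlation). Cfi, the protease that inactivates C3b, rose by 2.74 ± 0.27 (SE, adjusted p = 0.00107) on the log2 scale. C3ar1 and C5ar1, the receptors for the fragments C3a and C5a, rose by 3.15 ± 0.37 (SE, adjusted p = 0.00157) and 2.79 ± 0.45 (SE, adjusted p = 0.00397). Of 19 complement components 11 were higher and 3 lower, C3 included (11 and 3 adjusted over the list alone). Camera called these components at an adjusted p of 0.00207 (adjusted p = 0.105 with an estimated correlation). C4b, cleaved early in the cascade, was higher by 2.72, and C6, part of its terminal complex, by 3.62 ± 0.42 (SE). Mouse C3 itself fell by 3.81 ± 0.34 (SE, adjusted p = 0.0009), and Gpr108 rose by 1.75 ± 0.12 (SE, adjusted p = 0.000377). Since reads were assigned to the mouse build, this fall does not give the level of the humanized C3 transcript.

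Proximal tubule genes were called lower for 12 of 28 members and higher for 1 (15 and 1 adjusted over the list alone), with a median log2 fold change of -0.73. By camera the adjusted p was 4.74e-08 (adjusted p = 0.347 with an estimated correlation). They included Slc34a3, a phosphate transporter, at -1.54 and Slc5a2, a glucose transporter, at -1.18. All 22 oxidative phosphorylation genes were lower, 22 also adjusted over the list alone, with a median of -0.59. This list had a camera adjusted p of 3.88e-11 (adjusted p = 0.304 with an estimated correlation). In the 3 huC3 kidneys collected on the WT day, 12 of the 28 proximal tubule genes were lower and 2 higher with a median of -0.39, and 22 oxidative phosphorylation genes were lower. With the earlier animals kept in the fit as a group of their own, 7 proximal tubule genes were lower and 1 higher. In that fit 16 oxidative phosphorylation genes were lower. Of 23 podocyte genes 4 were higher and 0 lower (3 and 0 adjusted over the list alone), and the list was not called (camera adjusted p = 0.109), except without WT replicate 3 (median 0.36, adjusted p = 0.0156). Nphs1, nephrin, stood at 22.2 ± 5.92 CPM (SD, n = 6) against 23.9 ± 9.41 CPM (SD, n = 3; edgeR adjusted p = 0.788). Of 26 interferon response genes edgeR called 0 (0 adjusted over the list alone; 1 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom). The median of that list was -0.02 and its mean 0.04, so their signs differ (camera adjusted p = 0.994). Without WT replicate 2 that list was called, with a median of 0.51 (camera adjusted p = 0.0217).

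Among genes with no overlap between the groups, Arhgap36 had no count in the 3 WT libraries and 3.77 ± 1.34 CPM (SD, n = 6) in huC3, at least 38.0-fold higher against a floor of 0.0991 CPM over the WT group. Grem1, an antagonist of bone morphogenetic proteins, rose by 6.96 ± 1.01 (SE, adjusted p = 0.00285) on the log2 scale. Ugt1a2, a glucuronosyltransferase, went from 4.81 ± 3.59 (SD, n = 3) to 357 ± 207 CPM (SD, n = 6; adjusted p = 0.0027). Slc22a7, an organic anion transporter, fell by 4.22 ± 0.49 (SE, adjusted p = 0.00157). Slco1a1, another, fell by 3.88 ± 0.65 (SE, adjusted p = 0.00436). Pvalb, a calcium-binding protein of the distal tubule, fell by 3.10 ± 0.51 (SE, adjusted p = 0.00408).

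Of 14323 genes tested in experiment 2, edgeR called 4069, with 2358 higher and 1711 lower in huC3. Of these, 1348 and 225 changed at least 2-fold. The groups did not overlap in 33.2% of all genes tested, where chance gives 2.38%. Camera called 18 of 27 lists, 16 higher and 2 lower, and 0 with an estimated correlation (7 at an unadjusted p under 0.05; 19 by fry). The count fell to 1379, 1768 and 1930 when WT replicate 1, 2 or 3 was left out. With only the 3 huC3 animals collected on the WT day it was 3179, with 18 tubular injury, 30 matrix and 18 macrophage genes higher. In a fit that kept the earlier animals as a group of their own, the WT-day animals against WT gave 2035 calls. There 16 tubular injury, 29 matrix and 18 macrophage genes were higher.

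In experiment 3, control antibody huC3 kidneys were set against WT kidneys, the genotype comparison in the presence of a control antibody that the labels do not give for WT. Most injury, matrix and macrophage genes and all T cell and antigen presentation genes measured were called higher in the huC3 kidneys, and 16 of 28 proximal tubule and 21 of 22 oxidative phosphorylation genes were lower. Camera called these lists at a preset correlation, and none passed with an estimated one (adjusted p = 0.107 to 0.205). Lcn2 reached 48.8 ± 33.1 CPM (SD, n = 3) against 2.33 ± 0.631 CPM (SD, n = 5), a log2 fold change of 4.38 ± 0.58 (SE, adjusted p = 0.000168). Spp1 reached 2650 ± 1300 CPM (SD, n = 3) against 322 ± 34.2 CPM (SD, n = 5; log2 fold change 3.04 ± 0.26 SE, adjusted p = 3.13e-05). Kap stood at 5110 ± 1390 CPM (SD, n = 3) against 17260 ± 3980 CPM (SD, n = 5; edgeR adjusted p = 0.000267).

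Tubular injury genes were higher for 20 of 22 members and lower for 0 (20 and 0 adjusted over the list alone). Their median was 1.78 and their camera adjusted p 3.05e-11 (adjusted p = 0.174 with an estimated correlation). Havcr1 stood at 60.1 ± 52.5 CPM (SD, n = 3) against 4.51 ± 8.10 CPM (SD, n = 5), a log2 fold change of 3.73 ± 1.02 (SE, adjusted p = 0.0125). Its call was lost without control antibody replicate 3 (2.74, adjusted p = 0.0826) and in the WT run alone (3.07, adjusted p = 0.11). Without WT replicate 5, which held 19.0 CPM where the other WT libraries held at most 1.03 CPM, it was 6.07 (adjusted p = 0.000753). Matrix genes were higher for 30 of 33 and lower for 0 (31 and 0 adjusted over the list alone; camera adjusted p = 5.47e-31; adjusted p = 0.107 with an estimated correlation). Col1a1 stood at 101 ± 35.0 CPM (SD, n = 3) against 15.5 ± 5.07 CPM (SD, n = 5; adjusted p = 0.000157). Macrophage genes were higher for 20 of 21 and lower for 0 (20 and 0 adjusted over the list alone), T and NK cell genes for all 14 (14 adjusted over the list alone), and antigen presentation genes for all 19 (19 adjusted over the list alone). Their medians were 2.36, 2.38 and 1.60 and their camera adjusted p values 1.89e-15, 7.63e-09 and 2.12e-15 (adjusted p = 0.138 with an estimated correlation for each). Itgam rose by 3.24 ± 0.32 (SE), Cd4, the T helper cell coreceptor, by 3.76 and Cd74, the invariant chain of class II molecules, by 2.28 on the log2 scale. Of 26 interferon response genes 15 were higher and 0 lower (16 and 0 adjusted over the list alone). Gbp2 and Irf1, which interferon induces, lay at 1.86 and 1.46 among them (camera adjusted p = 7.55e-06; adjusted p = 0.273 with an estimated correlation).

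Complement regulators and receptors were higher for 12 of 17 and lower for 0 (12 and 0 adjusted over the list alone; camera adjusted p = 8.02e-09; adjusted p = 0.123 with an estimated correlation). Cfi rose by 2.84 ± 0.21 (SE, adjusted p = 1.5e-05) on the log2 scale. C3ar1 rose by 2.73 ± 0.31 (SE, adjusted p = 8.24e-05) and C5ar1 by 2.83 ± 0.40 (SE, adjusted p = 0.000248). Complement components were higher for 11 of 20 and lower for 3 (11 and 4 adjusted over the list alone; camera adjusted p = 0.000488; adjusted p = 0.138 with an estimated correlation). The acute phase list had 11 of 19 higher and 0 lower (11 and 0 adjusted over the list alone), and the coagulation list 13 of 24 higher and 3 lower (14 and 3 adjusted over the list alone). Their camera adjusted p values were 0.00134 and 0.00494 (adjusted p = 0.347 and adjusted p = 0.193 with an estimated correlation). The library labelled huC3 control antibody replicate 1 held abundant liver transcripts, with Alb at 144 CPM against 8.75 CPM in the lowest library of its group. The 5 WT libraries also held liver transcripts, with Alb at 27.2 to 64.1 CPM and 9.89 to 14.9 CPM of 7 liver-restricted transcripts in sum. Control antibody replicates 2 and 3, both of the huC3-only run, held 0.362 and 0.236 CPM of those 7. Without control antibody replicate 1 the calls were 11 higher and 5 lower for complement components, 8 and 2 for acute phase and 12 and 3 for coagulation. With all 3 control antibody libraries C3 was not called (log2 fold change -1.31, adjusted p = 0.129), and without that library it was called lower (-3.06, adjusted p = 0.00301). C3 was also called lower with the replicate block (-1.65, adjusted p = 0.0192). Gpr108 rose by 1.78 ± 0.09 (SE, adjusted p = 2.79e-07).

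Proximal tubule genes were lower for 16 of 28 and higher for 1 (17 and 1 adjusted over the list alone; median -0.47; camera adjusted p = 4.44e-09; adjusted p = 0.123 with an estimated correlation). Slc7a13, an amino acid transporter of the late proximal tubule, fell by 2.25 ± 0.24 (SE). Oxidative phosphorylation genes were lower for 21 of 22 and higher for 0 (22 and 0 adjusted over the list alone; median -0.46; camera adjusted p = 1.03e-08; adjusted p = 0.205 with an estimated correlation). Of 23 podocyte genes 10 were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 0.00549; adjusted p = 0.193 with an estimated correlation). The podocyte call was lost with the run as a term (median 0.16, camera adjusted p = 0.0743) and without control antibody replicate 2 (median 0.31, camera adjusted p = 0.0554). Nphs1 stood at 23.1 ± 5.02 CPM (SD, n = 3) against 19.3 ± 2.56 CPM (SD, n = 5; edgeR adjusted p = 0.279). Among genes without overlap between the groups, Gsta1, a glutathione transferase, rose by 6.60 ± 0.88 (SE), Ugt1a2 by 6.48 ± 0.70 (SE, adjusted p = 7.3e-05) and Timp1, an inhibitor of matrix proteases, by 4.44 ± 0.75 (SE). Slc22a7 fell by 4.87 ± 0.56 (SE, adjusted p = 8.48e-05).

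**Figure D2:**
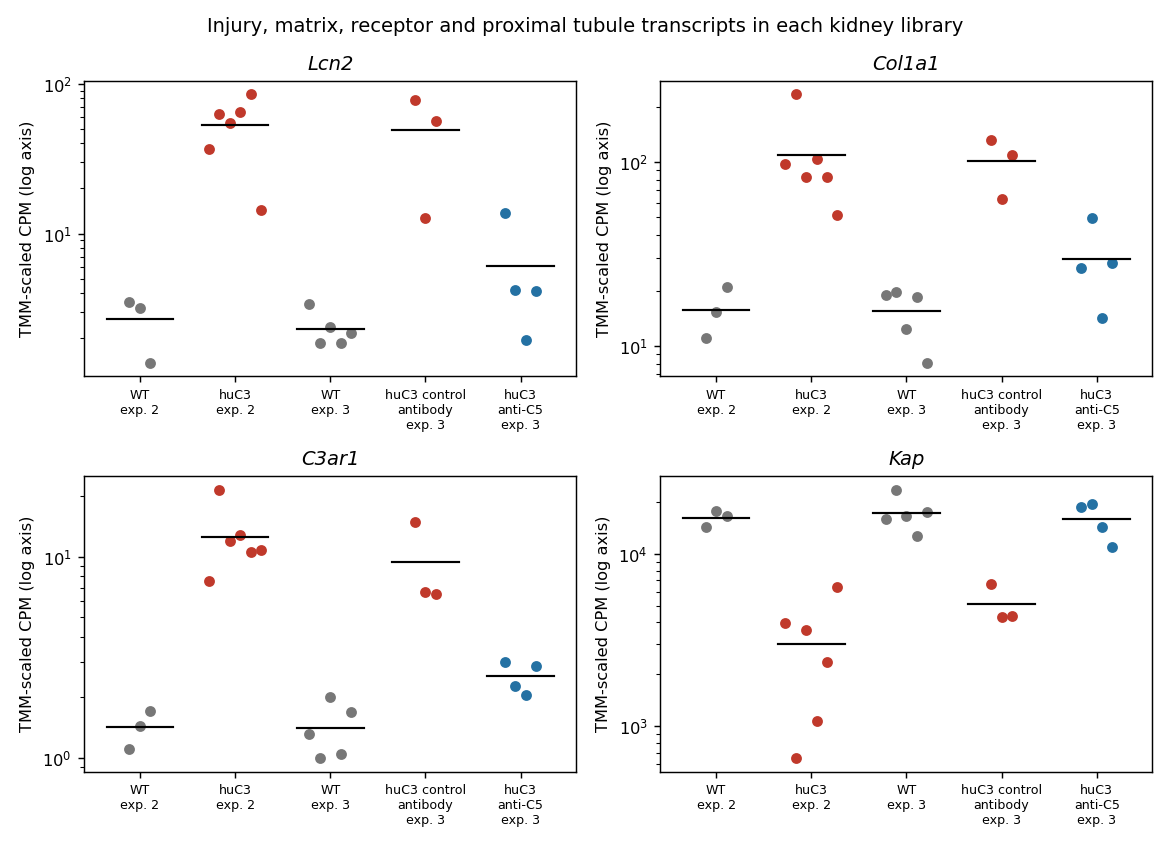
TMM-scaled CPM (log axis) of Lcn2, Col1a1, C3ar1 and Kap in each of the 21 kidney libraries, with group means as lines. Mean Lcn2 was 48.8 CPM with control antibody, 6.04 CPM with anti-C5 and 2.33 CPM in WT kidneys of experiment 3.

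Of 14464 genes tested, edgeR called 5306 in this comparison, 2859 higher and 2447 lower, of which 1452 and 362 changed at least 2-fold. Groups did not overlap in 37.0% of genes tested, where chance gives 3.57%. Camera called 20 of 27 lists, 17 higher and 3 lower, and 0 with an estimated correlation (9 at an unadjusted p under 0.05; 21 by fry). Without the library labelled huC3 control antibody replicate 1, 4529 genes were called, 4051 of them shared, and 17 tubular injury, 30 matrix and 19 macrophage genes were higher. With the run of submitter numbers as a term the count was 4173 and in the WT run alone, with 1 control antibody library assumed to vary like the others, it was 4273, while the huC3-only run held no WT.

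Anti-C5 treatment was compared with control antibody within huC3 mice of experiment 3, to ask what blocking C5 changed in the kidney. Most injury, matrix, macrophage, T cell, antigen presentation and cell division genes were called lower with anti-C5, and 13 of 28 proximal tubule genes and 17 of 20 heat shock chaperones were higher. Camera called these lists at a preset correlation, and none of the lists fixed beforehand passed with an estimated one (adjusted p = 0.0945 to 0.16). Lcn2 fell by 3.01 ± 0.58 (SE) on the log2 scale (adjusted p = 0.00398), to 6.04 ± 5.28 CPM (SD, n = 4) from 48.8 ± 33.1 CPM (SD, n = 3). Col1a1 fell by 1.76 ± 0.37 (SE, adjusted p = 0.00609), to 29.7 ± 14.6 CPM (SD, n = 4). Spp1 fell by 2.15 ± 0.28 (SE, adjusted p = 0.000995), to 598 ± 175 CPM (SD, n = 4). Kap rose by 1.63 ± 0.26 (SE, adjusted p = 0.00178), to 15850 ± 3980 CPM (SD, n = 4).

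Of 22 tubular injury genes 14 were lower and 0 higher with anti-C5 (19 and 0 adjusted over the list alone). Their median was -1.51 and their camera adjusted p 4.47e-11 (adjusted p = 0.16 with an estimated correlation). Havcr1 stood at 8.13 ± 9.99 CPM (SD, n = 4) against 60.1 ± 52.5 CPM (SD, n = 3) and was not called by edgeR (adjusted p = 0.067) or DESeq2 (adjusted p = 0.0911). It was called by limma-voom (adjusted p = 0.0128), on the 2 TPM scales (adjusted p = 0.0142 and 0.0232), with the replicate block (adjusted p = 0.0278), and without control antibody replicate 2 (adjusted p = 0.0496) or anti-C5 replicate 1 (adjusted p = 0.0228). Matrix genes were lower for 26 of 33 and higher for 0 (30 and 0 adjusted over the list alone; camera adjusted p = 3.63e-22; adjusted p = 0.0945 with an estimated correlation). Col15a1, a basement membrane collagen chain, was among them at -2.11 ± 0.26 (SE). Macrophage genes were lower for 20 of 21 and higher for 0 (20 and 0 adjusted over the list alone), T and NK cell genes for 12 of 14 (13 adjusted over the list alone), and antigen presentation genes for 18 of 19 (19 adjusted over the list alone). Medians were -1.90, -1.90 and -1.57 and camera adjusted p values 7.6e-15, 5.32e-09 and 2.66e-20 (adjusted p = 0.101, adjusted p = 0.108 and adjusted p = 0.0945 with an estimated correlation). Itgam fell by 2.73 ± 0.34 (SE, adjusted p = 0.000995) on the log2 scale, and Cd74 lay at -1.93. Cell division genes were lower for 16 of 21 and higher for 0 (17 and 0 adjusted over the list alone; camera adjusted p = 1.8e-12; adjusted p = 0.0945 with an estimated correlation). Mki67 lay at -2.01. Interferon response genes were lower for 13 of 26 and higher for 0 (20 and 0 adjusted over the list alone; camera adjusted p = 3.1e-07; adjusted p = 0.245 with an estimated correlation).

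Complement regulators and receptors were lower for 9 of 17 and higher for 0 (11 and 1 adjusted over the list alone; camera adjusted p = 2.6e-07; adjusted p = 0.0945 with an estimated correlation). C3ar1 fell by 1.88 ± 0.32 (SE, adjusted p = 0.00233) on the log2 scale. C5ar1 lay at -1.98 ± 0.41 (SE, adjusted p = 0.00572) and Cfi at -1.56 ± 0.21 (SE). Complement components were lower for 11 of 20 and higher for 2 (13 and 3 adjusted over the list alone; camera adjusted p = 2.34e-05; adjusted p = 0.0945 with an estimated correlation). C1qc, a chain of C1q, lay at -1.94. C3 was called lower (log2 fold change -2.81, adjusted p = 0.0219), and the size and the call depended on the library labelled huC3 control antibody replicate 1. Without that library C3 was lower but not called (-1.05, adjusted p = 0.285), nor was it called without anti-C5 replicate 2 (-2.48, adjusted p = 0.0662). The call was also lost with limma-voom (adjusted p = 0.16), on log2(TPM + 1) (adjusted p = 0.0986), with only the 2 groups in the fit (adjusted p = 0.0543) and in the huC3-only run (-0.68, adjusted p = 0.489). The acute phase list had 9 of 19 lower and 0 higher (14 and 0 adjusted over the list alone), and the coagulation list 10 of 24 lower and 2 higher (14 and 2 adjusted over the list alone). Their camera adjusted p values were 7.44e-06 and 0.00175 (adjusted p = 0.223 and adjusted p = 0.172 with an estimated correlation). Without that library, which held liver transcripts with Alb at 144 CPM, the calls were 9 lower and 2 higher for complement components, 6 and 0 for acute phase and 6 and 2 for coagulation.

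Proximal tubule genes were higher for 13 of 28 and lower for 1 (18 and 1 adjusted over the list alone; median 0.47; camera adjusted p = 8.88e-09; adjusted p = 0.0945 with an estimated correlation). Slc7a13 rose by 1.76 ± 0.24 (SE, adjusted p = 0.00111). Of 22 oxidative phosphorylation genes 2 were higher and 0 lower by edgeR (0 and 0 adjusted over the list alone; 13 higher at an unadjusted p under 0.05, 9 by DESeq2 and 4 by limma-voom), with a median of 0.25 (camera adjusted p = 0.000162; adjusted p = 0.401 with an estimated correlation). On the log2(TPM + 1) scale the median was -0.08, or 0.195 above the median of all genes. Of 20 heat shock chaperones, a list written after this comparison had been seen and so no independent evidence of its direction, 17 were higher and 0 lower (18 and 0 adjusted over the list alone). Its median was 1.10 (camera adjusted p = 8.49e-25; adjusted p = 0.0112 with an estimated correlation). Hsph1 rose by 2.30 ± 0.23 (SE, adjusted p = 0.000546), to 343 ± 101 CPM (SD, n = 4) from 69.9 ± 9.52 CPM (SD, n = 3). Podocyte genes were higher for 1 of 23 and lower for 2 (0 and 1 adjusted over the list alone; camera adjusted p = 0.955), with Nphs1 at a log2 fold change of 0.22 (edgeR adjusted p = 0.421). Gpr108 was not called, at 0.19 ± 0.09 (SE, adjusted p = 0.145). Among genes without overlap between the groups, Slc22a7 rose by 4.10 ± 0.55 (SE, adjusted p = 0.000995). Ifi44l, Gbp2b, Ugt1a2 and Socs3 lay at log2 fold changes of -5.79, -7.15, -4.83 and -3.65. Ifi44l and Gbp2b are interferon-induced genes, and Socs3 encodes a feedback inhibitor of cytokine signalling.

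**Figure D3:**
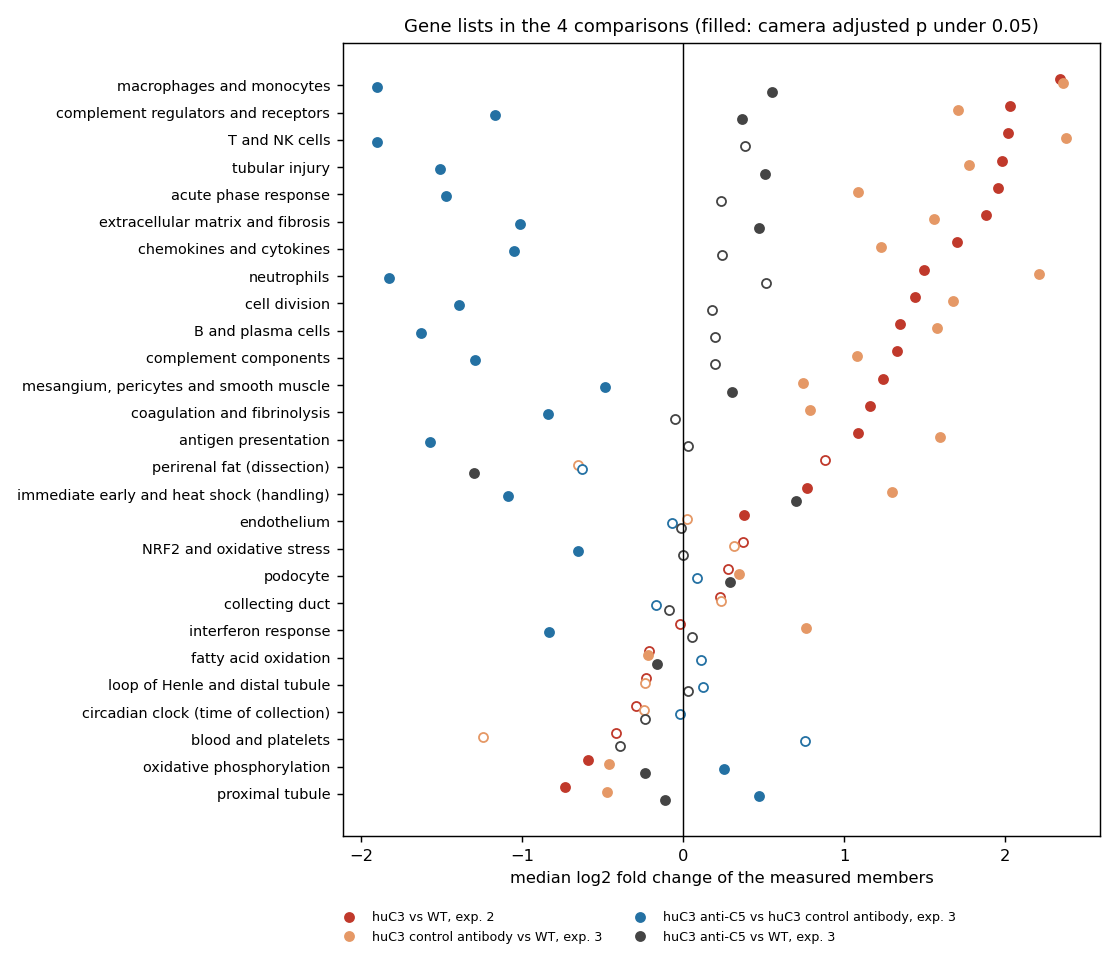
Median log2 fold change of the measured members of each of 27 gene lists in the 4 comparisons, with filled points for a camera adjusted p under 0.05 at the preset correlation of 0.01. The macrophage list lay at 2.34 and 2.36 in the genotype comparisons, at -1.90 for anti-C5 against control antibody and at 0.55 for anti-C5 against WT.

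For anti-C5 against control antibody edgeR called 3069 of 14464 genes, 1263 higher and 1806 lower. Of these 200 and 969 changed at least 2-fold. No overlap between groups was seen for 27.6% of genes tested, where chance gives 5.71%. Camera called 19 of 27 lists, 2 higher and 17 lower, and 0 with an estimated correlation (9 at an unadjusted p under 0.05; 19 by fry). Without the library labelled huC3 control antibody replicate 1 the count was 2241, of which 1968 were shared, with 13 tubular injury, 25 matrix and 13 macrophage genes lower, and without control antibody replicate 3 it was 1643. Within the WT run, with control antibody replicate 1 alone against 2 and assumed to vary like the others, it was 1890, and within the huC3-only run, 2 against 2, it was 23 (2661 at an unadjusted p under 0.05), where 93.5% of the 1805 calls of the WT run measured in both had the same sign.

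Anti-C5 kidneys were also compared with WT kidneys, to ask what still differed from WT under the antibody. Grem1, Cyp27b1 and Cfi were higher and mouse C3 was lower in anti-C5 kidneys, and edgeR called no matrix or tubular injury gene on its own, where DESeq2 called 8 and 1 and limma-voom 0 (21 and 4 at an unadjusted p under 0.05). Grem1 stood at 6.98 ± 5.68 CPM (SD, n = 4) against 0.562 ± 0.466 CPM (SD, n = 5; log2 fold change 3.63 ± 0.63 SE, adjusted p = 0.0454). Cyp27b1, which makes the active form of vitamin D, stood at 25.2 ± 7.67 CPM (SD, n = 4) against 5.64 ± 2.77 CPM (SD, n = 5; adjusted p = 0.0183). Cfi rose by 1.28 ± 0.20 (SE, adjusted p = 0.0393) on the log2 scale.

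The matrix list had a median log2 fold change of 0.47 against WT, with 0 of 33 members called by edgeR (19 higher and 0 lower adjusted over the list alone). There were 21 at an unadjusted p under 0.05, 8 by DESeq2, 0 by limma-voom and 1 by edgeR with the run as a term. Its camera adjusted p was 4.27e-12 (adjusted p = 0.485 with an estimated correlation). Tubular injury and macrophage lists had medians of 0.51 and 0.55, with 0 members called by edgeR in either (0 adjusted over the list alone; 4 and 8 at an unadjusted p under 0.05, 1 and 0 by DESeq2, 0 by limma-voom, 0 and 1 by edgeR with the run as a term). Their camera adjusted p values were 0.0132 and 0.002 (adjusted p = 0.839 and adjusted p = 0.815 with an estimated correlation). Both list calls were lost without anti-C5 replicate 1 (medians 0.17 and 0.25, camera adjusted p = 0.46 and 0.196), and that of tubular injury without WT replicate 2 (0.42, camera adjusted p = 0.0704). Podocyte genes were higher for 1 of 23 and lower for 0 (9 and 0 adjusted over the list alone; median 0.29; camera adjusted p = 1.03e-07; adjusted p = 0.185 with an estimated correlation). Complement regulators were higher for 1 of 17 (2 adjusted over the list alone; median 0.37; camera adjusted p = 0.00461; adjusted p = 0.57 with an estimated correlation), a call also lost without anti-C5 replicate 1 (0.31, camera adjusted p = 0.0686). Of 20 complement components 1, C3, was lower and 0 higher (2 and 3 adjusted over the list alone; camera adjusted p = 0.932), and the list's median of 0.20 differs in sign from its mean of -0.16. Single genes not called included Lcn2 at 1.37 ± 0.58 (SE, adjusted p = 0.231) and Havcr1 at 0.85 ± 1.01 (SE, adjusted p = 0.674). Col1a1 lay at 0.95 ± 0.34 (SE, adjusted p = 0.169) and Nphs1 at 0.48 ± 0.16 (SE, adjusted p = 0.159). C3ar1 and C5ar1 lay at 0.84 ± 0.31 (SE, adjusted p = 0.18) and 0.86 ± 0.41 (SE, adjusted p = 0.278). Kap stood at 15850 ± 3980 CPM (SD, n = 4) against 17260 ± 3980 CPM (SD, n = 5; edgeR adjusted p = 0.791).

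The genotype difference at the modified locus was present in this comparison, with Gpr108 higher by 1.98 ± 0.08 (SE, adjusted p = 3.61e-08) and C3 at -4.12 ± 0.73 (SE, adjusted p = 0.0454). Other called genes were Sult1c2, a sulfotransferase, at 1.14 ± 0.16 (SE, adjusted p = 0.0183), and Aldh1a2, which makes retinoic acid, at 1.74 ± 0.30 (SE). Ahsa2, an activator of the chaperone HSP90, lay at 0.93 ± 0.13 (SE, adjusted p = 0.0183). Ifi44l fell by 5.00 ± 0.89 (SE) on the log2 scale. Apobec2, a cytidine deaminase relative, fell by 5.38 ± 0.85 (SE, adjusted p = 0.0393). Of 14464 genes edgeR called 26, 18 higher and 8 lower, with 2742 at an unadjusted p under 0.05. On simulated counts of this design edgeR recovered 37.3% of genes changed 1.5-fold, so smaller differences can go uncalled. Groups did not overlap in 8.89% of genes tested, where chance gives 1.59%. Camera called 11 of 27 lists, 7 higher and 4 lower, and 0 with an estimated correlation (2 at an unadjusted p under 0.05; 1 by fry). On simulated counts of this design DESeq2 made 25 false calls among 185, and edgeR 6 among 144. The count of called genes was 611 with DESeq2, 10 with limma-voom, 12 with the replicate block, 92 with the run as a term and 123 in the WT run alone. It was 7, 8, 1 and 2 without WT replicate 1, 3, 4 or 5 and 12, 9, 2 and 1 without anti-C5 replicate 1, 2, 3 or 4, and each named call here but that of Gpr108 was lost without WT replicate 4 or 5 or anti-C5 replicate 3 or 4.

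The genes called in experiment 2 were then followed in experiment 3, with which it shares no library. Genes higher in huC3 kidneys of experiment 2 were mostly higher with control antibody and lower after anti-C5, and those lower in experiment 2 went the other way. Of 2299 measured genes of the higher set, 98.0% lay above 0 for control antibody against WT, with a median log2 fold change of 0.96, and 1754 were called higher and 1 lower. For anti-C5 against control antibody 96.1% lay below 0, with a median of -0.74, and 1246 were called lower and 2 higher. For anti-C5 against WT 78.1% lay above 0, with a median of 0.20, and 7 were called higher and 0 lower. In the lower set of 1711 genes, 95.7% lay below 0 for control antibody against WT (median -0.46; 1159 called lower, 3 higher) and 96.3% above 0 for anti-C5 against control antibody (median 0.35; 692 called higher, 2 lower). Against WT, 71.6% of that set lay below 0 with anti-C5 (median -0.12; 3 called lower, 1 higher). Camera gave p = 3.12e-81 and 2.09e-49 for control antibody against WT (p = 0.00101 and p = 0.00261 with an estimated correlation). For anti-C5 against control antibody it gave p = 1.79e-69 and 8.73e-46 (p = 0.00161 and p = 0.00342 with an estimated correlation). For anti-C5 against WT it gave p = 2.04e-13 and 3.15e-09 (p = 0.086 and p = 0.139 with an estimated correlation). Thsd4, a matrix-associated protein, was higher by 1.64 with control antibody against WT and fell by 1.18 with anti-C5. Cirbp, a cold-inducible RNA-binding protein, fell by 1.82 with anti-C5.

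**Figure D4:**
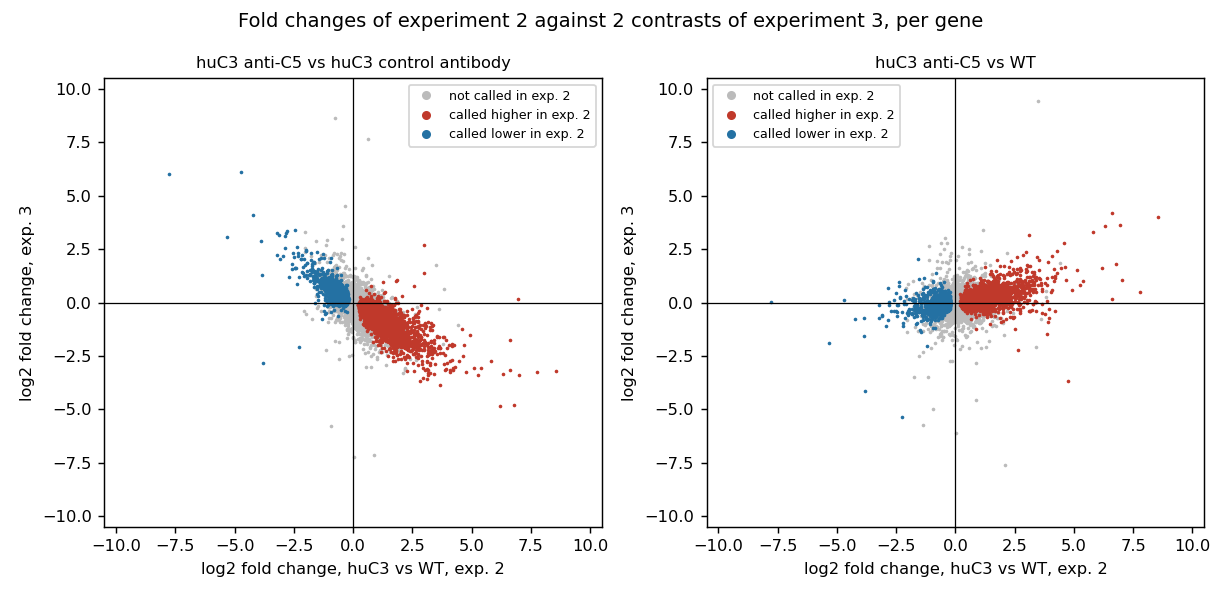
Log2 fold change of each gene for huC3 against WT in experiment 2 (horizontal axis) against anti-C5 versus control antibody and anti-C5 versus WT in experiment 3 (vertical axes), coloured by the call of experiment 2. Of the genes called higher in experiment 2, 96.1% lay below 0 for anti-C5 against control antibody and 78.1% above 0 for anti-C5 against WT.

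Within experiment 3, the comparisons of control antibody with WT and of anti-C5 with control antibody share the 3 control antibody libraries, which alone makes their fold changes run in opposite directions. Across 14464 genes, which are not independent replicates, their correlation was -0.84 against a mean of -0.594 in 20 simulations. Their covariance was -0.475 against -0.0537. The simulations held neither a genotype nor a treatment effect and drew each gene independently. A simulation that kept the genotype effect was not run. Signs were opposite for 82.2% of genes, against a mean of 70.3% in the simulations.

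The huC3 effect itself was compared between the experiments by an interaction test over 14748 genes. Interferon response genes lay 0.795 higher in the genotype effect of experiment 3 than in that of experiment 2 (camera adjusted p = 9.75e-09; adjusted p = 0.832 with an estimated correlation), and antigen presentation genes 0.306 higher (camera adjusted p = 0.00596; adjusted p = 0.832 with an estimated correlation). The interferon median of experiment 2 was -0.02 with all libraries and 0.506 without WT replicate 2, against 0.766 in experiment 3. The list difference was not computed with libraries left out, so how far it rests on that 1 animal is open. On simulated counts the interaction fit recovered 46.3% of genes changed 2-fold and 4.48% of those changed 1.5-fold. By single genes edgeR called 0 (1133 at an unadjusted p under 0.05). The count was 56 without the library labelled huC3 control antibody replicate 1, 2 without huC3 replicate 2, 1 without huC3 replicate 5 and 1 without control antibody replicate 3. The control antibody was given in experiment 3 only, so any effect of it cannot be told apart from other differences between the experiments.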

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

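The tests of the chaperones against WT, of Gpr108 against the kidney state that anti-C5 lowered and of splits within a run or day were chosen after the result was seen; the liver and chaperone lists were written after some of their members had been seen. In 33 sets of values of 4 to 6 libraries, 4 libraries stood apart from the rest of their group, and chance gives about 1 in 20 sets, or 1.6. Col1a1 in huC3 replicate 2 of experiment 2 stood at 233 CPM, with the nearest library at 104 CPM. Havcr1 in WT replicate 5 of experiment 3 stood at 19.0 CPM, with the nearest at 1.03 CPM. C3 in anti-C5 replicate 2 stood at 0.445 CPM, with the nearest at 1.35 CPM. Havcr1 in anti-C5 replicate 1 stood at 23.0 CPM, with the nearest at 4.77 CPM.

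The genotype effect differed between experiments 3 and 2 for 4 of 27 lists by camera at the preset correlation. The difference was -0.258 for endothelium (adjusted p = 0.00169), -0.427 for mesangium, pericytes and smooth muscle (adjusted p = 0.00258), 0.795 for the interferon response (adjusted p = 9.75e-09) and 0.306 for antigen presentation (adjusted p = 0.00596). With an estimated correlation none of the 4 passed (adjusted p = 0.832 for each). None of these differences was computed with libraries left out. Without WT replicate 2 the interferon median of experiment 2 moved from -0.02 to 0.506.

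Mouse C3 lay at the WT level in the library labelled huC3 control antibody replicate 1. A WT library under a huC3 label is argued against by Gpr108, which lay 1.6 (log2) above the highest WT library, where the 5 WT libraries span 0.389. An animal with 1 mouse and 1 humanized allele is argued against by Gpr108 at 80.5 CPM, above the lowest of the other 6 huC3 libraries (79.1 CPM) and far from the midpoint of 56.5 CPM, where Gpr108 scales with the number of humanized alleles, which was not tested. RNA from liver that holds mouse C3 stays open as a candidate source, since 31 abundant liver transcripts, of which 19 were also measured in the kidneys of experiment 2, had a median excess of 3.04 (log2) over the other 2 libraries of the group, with 25 above both, Alb at 144 CPM and Ttr at 466 CPM. Of 7 liver-restricted transcripts this library held 87.3 CPM in sum, anti-C5 replicate 1 held 14.8 CPM with C3 at 1.35 CPM, below the 2.79 CPM that a constant ratio would give, but 2 single animals do not decide this, and no other biological explanation was tested.

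Heat shock chaperones were higher with anti-C5 than with control antibody. The run of submitter numbers and its collection day as the whole cause are argued against by a median of 0.999 with the run as a term (camera p = 7.43e-25; p = 0.00222 with an estimated correlation). Time of day was approached with the first component of the circadian list, which took 56.7% of that list's variance. With that component as a covariate the chaperone median was 1.13 (camera p = 1.21e-30 at the preset correlation). Whether the component follows time of day was not tested, and the chaperone list was written from this comparison. Time of day therefore stays open. Whether a return from the untreated huC3 state to the WT level is the whole change stays open, since the list was written from these anti-C5 libraries. For anti-C5 against WT the median was 0.608 (camera adjusted p = 1.26e-13). With an estimated correlation the camera p was 0.0215 unadjusted and 0.0646 adjusted over the later lists. With the run as a term the median was 0.701 (unadjusted camera p = 0.00348 with an estimated correlation). Leaving out animals in turn, that median without the run term ran from 0.493 to 0.69. The highest unadjusted camera p with an estimated correlation was then 0.0534, without anti-C5 replicate 2. A kidney change that goes with the untreated huC3 state stays open as well. The chaperones were lower in huC3 than in WT in experiment 2, with a median of -0.593 (camera p = 2.53e-08, and p = 0.0844 with an estimated correlation). Handling that differed between the groups may also contribute, which was not tested. The immediate early and heat shock list had 4 of 18 genes higher and 10 lower with anti-C5 (5 and 12 adjusted over the list alone). It holds chaperones such as Hsph1, so its counts are no separate evidence on handling.

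Gpr108 was higher in huC3 kidneys in every comparison with WT. The kidney state that anti-C5 lowered is argued against as its cause, since the 95% interval of its log2 fold change with anti-C5 ran from -0.00205 to 0.391. Strain alleles carried along with the modified C3 locus stay open as a candidate explanation, since within 10 Mb of C3, beside C3 and Gpr108, 2 of 96 genes were called between anti-C5 and WT, Apobec2 and Sult1c2, against 22 of 13783 elsewhere (one-sided Fisher's exact p = 0.0118). Both calls were lost without WT replicate 4 or 5 or anti-C5 replicate 3 or 4 (adjusted p = 0.0542 to 0.117), and the same test did not pass in experiment 2 (31.9% against 28.4%, one-sided Fisher's exact p = 0.257) or for control antibody against WT (44.8% against 36.9%, p = 0.0687). The construct may also change Gpr108 transcription directly, which was not tested.

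Splits of the same libraries into groups of the same sizes were used to ask how often other groupings give as many calls. In experiment 2, 1 of 84 splits, the real one, gave as many calls (4069), a share of 0.0119 over splits that ignore the collection day. The highest of the others, 3402, set the 3 earlier-collected huC3 animals against the WT and the other huC3 animals, so genotype also feeds these calls. Within huC3 kidneys the earlier against the WT-day animals gave 1394 calls, where collection day and age cannot be separated. The count within the WT day was 3179, or 2035 with the earlier animals kept in the fit as a group of their own. For control antibody against WT it was 1 of 56 splits (5306, highest other 5), and for anti-C5 against control antibody 1 of 35 (3069, highest other 636). These are shares of 0.0179 and 0.0286 over splits that ignore the run. With libraries exchanged only within a day or run, the splits numbered 20, 6 and 18 in these 3 comparisons (highest other 0, 0 and 636), too few for a share under 0.05. For anti-C5 against WT 1 of 100 drawn splits, the real one, reached 26 calls (highest other 7). Within the run it was 1 of 21 (highest other 4), a share of 0.0476 and the smallest that 21 splits can give. The count ran from 1 to 23 with animals left out in turn, so chance is not excluded for these calls.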

How the results depend on the processing

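Chosen after the data were seen were the huC3-only run alone, the lists in the experiment 2 animals collected on the WT day and the experiment 2 sets without chaperones. So was the fit with the earlier huC3 animals of experiment 2 as a group of their own. The other alternatives were planned. Leaving out the animals in turn, the count of called genes ran from 1379 to 5055 in experiment 2, from 3791 to 5228 for control antibody against WT, from 1643 to 3600 for anti-C5 against control antibody and from 1 to 23 for anti-C5 against WT. The libraries whose omission moved these counts most were WT replicates 1, 2 and 3 in experiment 2 (1379, 1768 and 1930), control antibody replicate 3 (1643), and, for anti-C5 against WT, WT replicates 1, 3, 4 and 5 (7, 8, 1 and 2) and anti-C5 replicates 1 to 4 (12, 9, 2 and 1). Called lists ran from 17 to 20, 20 to 21, 19 to 20 and 8 to 12 in the same order. Medians of the experiment 2 sets ran from 0.865 to 1.10 and -0.513 to -0.426 for control antibody against WT, from -0.876 to -0.658 and 0.316 to 0.410 for anti-C5 against control antibody, and from 0.163 to 0.236 and -0.147 to -0.0989 for anti-C5 against WT. The interaction count ran from 0 to 56, with 56 without control antibody replicate 1, 2 without huC3 replicate 2, 1 without huC3 replicate 5 and 1 without control antibody replicate 3.

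Of the other alternatives, 9 of 13 left the count within 1.5 times in experiment 2, 13 of 14 for control antibody against WT, 11 of 15 for anti-C5 against control antibody and 4 of 14 for anti-C5 against WT. A minimum absolute log2 fold change of 1, which by construction lowers a count, gave 1573, 1814, 1169 and 12. In experiment 2 the count was 6750 with age as a covariate, 7779 on log2(TPM + 1) and 7984 on log2(TPM + 0.1), where 95.9% and 96.0% of calls were higher, since the TPM scale moved the median of all genes by 0.42 and 0.47. The TPM shift was 0.19 and 0.212 for control antibody against WT and -0.279 and -0.313 for anti-C5 against control antibody. Relative to it, proximal tubule genes of experiment 2 lay at -0.778 and -0.827 and oxidative phosphorylation genes at -0.56 and -0.61. For anti-C5 against control antibody the count was 1890 in the WT run, 23 in the huC3-only run and 1745 with only the 2 groups in the fit, each with fewer samples. For anti-C5 against WT it was 16 with robust empirical Bayes, 12 with the replicate block, 611 with DESeq2, 10 with limma-voom, 5 and 5 on the 2 TPM scales, 92 with the run as a term, 123 in the WT run and 171 with only the 2 groups in the fit; the cause was not tested. The replicate block gave 3207, 4619 and 2591 in the other comparisons, and replicate numbers did not pair the animals throughout. Between control antibody and anti-C5, replicates 1 shared birth date, age and run, as did replicates 3, while replicates 2 did not. In that comparison the library of the same number correlated best for 1 of 3 pairs. With an estimated correlation 0 lists passed in any of the 4 comparisons, and the experiment 2 sets against WT, at 0.203 and -0.119, did not pass (camera p = 0.086 and 0.139). With the earlier huC3 animals of experiment 2 as a group of their own, complement components, complement regulators and tubular injury did pass for WT-day animals against WT (camera adjusted p = 0.0335 for each). With the WT-day animals alone the interaction count was 11.

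Genes that changed sign were not called in the comparison concerned, and the cause was not tested. Nphs1 in experiment 2 (-0.10) was 0.26 without WT replicate 3, 0.00291 without huC3 replicate 2, 0.33 and 0.38 on the TPM scales and 0.0171 in the WT-day animals. For control antibody against WT, Hc (0.83) was -0.74 without control antibody replicate 1, and Nphs1 (0.26) was -0.00111 with the run as a term and -0.12 in the WT run. For anti-C5 against control antibody on the TPM scales, Gpr108 (0.19) was -0.13 and -0.13, and Nphs1 (0.22) -0.10 and -0.11. For anti-C5 against WT, Havcr1 (0.85) was -0.47 without anti-C5 replicate 1, and Kap (-0.12) was 0.0162 and 0.0199 without WT replicate 2 or anti-C5 replicate 4, 0.15 with the run as a term and 0.14 in the WT run. Leaving out animals in turn, Nphs1 ran from -0.27 to 0.26 in experiment 2, Hc from -0.74 to 1.41 for control antibody against WT, and, against WT, Havcr1 from -0.47 to 3.19 and Kap from -0.24 to 0.0199. Depth limits Hc, with at most 58 counts per library, and C3 in huC3 kidneys, with as few as 10.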

Other observations

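The comparisons within huC3 kidneys by collection day and the lists of liver transcripts and cold-inducible proteins were chosen after the data had been seen, while the other lists were fixed before. Smooth muscle, pericyte and mesangial genes were higher in huC3 than in WT for 10 of 15 members in experiment 2 (11 adjusted over the list alone; camera adjusted p = 1.23e-05; adjusted p = 0.219 with an estimated correlation), with Acta2, smooth muscle actin, at a log2 fold change of 2.02. They were higher for 8 of 15 with control antibody against WT (8 adjusted over the list alone; camera adjusted p = 0.000138; adjusted p = 0.176 with an estimated correlation). With anti-C5 against control antibody 8 of 15 were lower (9 adjusted over the list alone; camera adjusted p = 0.0048; adjusted p = 0.278 with an estimated correlation). Chemokines and cytokines were higher for 17 of 24 and lower for 1 in experiment 2 (18 and 1 adjusted over the list alone), Ccl2, which attracts monocytes, at 4.68 ± 0.67 (SE) among them. With control antibody against WT 16 of 21 were higher and 1 lower (17 and 1 adjusted over the list alone), and with anti-C5 against control antibody 15 were lower and 0 higher (17 and 1 adjusted over the list alone). Camera adjusted p values were 6.6e-10, 1.8e-09 and 1.15e-10 (adjusted p = 0.144, adjusted p = 0.138 and adjusted p = 0.0945 with an estimated correlation).

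Neutrophil genes were higher for 3 of 6 in experiment 2 and 5 of 6 with control antibody against WT, and lower for 3 of 6 with anti-C5 against control antibody (3, 5 and 5 adjusted over the list alone; camera adjusted p = 0.00408, 0.00352 and 0.00276; adjusted p = 0.304, adjusted p = 0.193 and adjusted p = 0.194 with an estimated correlation). B and plasma cell genes were higher for 4 of 8 and 4 of 6 and then lower for 3 of 6 (4, 5 and 4 adjusted over the list alone; camera adjusted p = 0.0485, 0.0292 and 0.00615; adjusted p = 0.304, adjusted p = 0.273 and adjusted p = 0.219 with an estimated correlation). The B and plasma cell call was lost in experiment 2 without WT replicate 2 or 3 or huC3 replicate 6 (camera adjusted p = 0.054, 0.0516 and 0.0793) and with the replicate block (camera adjusted p = 0.0532). For control antibody against WT it was lost without control antibody replicate 1 (camera adjusted p = 0.0798). Endothelial genes were higher for 8 of 23 in experiment 2 (8 adjusted over the list alone; camera adjusted p = 0.0025; adjusted p = 0.434 with an estimated correlation), Selp, which tethers leukocytes, at 3.10 among them. With only the huC3 animals collected on the WT day 1 of 23 was higher, with a median of 0.172, and the endothelial list was not called (camera adjusted p = 0.129). In experiment 3 that list was not called (camera adjusted p = 0.593, 0.463 and 0.932 for control antibody against WT, anti-C5 against control antibody and anti-C5 against WT). Immediate early and heat shock genes had 7 of 18 higher and 1 lower in experiment 2, 11 and 1 with control antibody against WT, and 4 higher and 10 lower with anti-C5 against control antibody (8 and 2, 11 and 1, and 5 and 12 adjusted over the list alone). Camera adjusted p values were 0.0106, 0.000146 and 0.0122 (adjusted p = 0.388, adjusted p = 0.19 and adjusted p = 0.364 with an estimated correlation). The first was lost without WT replicate 3 (camera adjusted p = 0.0832) and the last without anti-C5 replicate 3 or 4 (camera adjusted p = 0.0943 and 0.059). Fos, an immediate early transcription factor, rose by 2.86 with control antibody against WT and fell by 2.01 with anti-C5, while Hsph1 of the same list went the other way. In experiment 2 the antigen presentation list had 12 of 19 higher (16 adjusted over the list alone), the acute phase list 11 of 18 higher and 1 lower (14 and 1 adjusted over the list alone) and the coagulation list 12 of 21 higher and 2 lower (13 and 2 adjusted over the list alone). Their camera adjusted p values were 2.52e-07, 1.92e-06 and 0.00106 (adjusted p = 0.347, adjusted p = 0.289 and adjusted p = 0.144 with an estimated correlation). Cell division genes were higher for 18 of 21 with control antibody against WT (18 adjusted over the list alone; camera adjusted p = 3.05e-11; adjusted p = 0.107 with an estimated correlation).

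The loop of Henle list was not called in experiment 2 (camera adjusted p = 0.0611) or in the 3 contrasts of experiment 3 (camera adjusted p = 0.59, 0.498 and 0.952), nor was the collecting duct list (0.271, 0.593, 0.288 and 0.584), the circadian list (0.271, 0.529, 0.498 and 0.92) or the blood and platelet list (0.168, 0.0692, 0.233 and 0.16). Some of these lists were called under single settings. The loop of Henle list was called in experiment 2 without WT replicate 1 or huC3 replicate 1, 2, 3 or 5 and in the WT-day animals (camera adjusted p = 0.0133 to 0.0457), and the collecting duct list for anti-C5 against control antibody without control antibody replicate 3 (camera adjusted p = 0.0323). With the run as a term the circadian list was called for control antibody against WT and anti-C5 against WT (camera adjusted p = 0.00285 and 0.000132). The blood and platelet list was called for control antibody against WT without WT replicate 3 or control antibody replicate 1 (camera adjusted p = 0.034 and 0.013), for anti-C5 against control antibody without control antibody replicate 1 or anti-C5 replicate 3 (camera adjusted p = 0.0405 and 0.00245) and for anti-C5 against WT without anti-C5 replicate 2 or 4 (camera adjusted p = 0.0362 and 0.0268). The circadian list's median and mean differed in sign in experiment 2 and for anti-C5 against control antibody. Fatty acid oxidation genes were lower for 9 of 24 and higher for 1 with control antibody against WT (9 and 1 adjusted over the list alone; camera adjusted p = 0.0302; adjusted p = 0.549 with an estimated correlation), with Acadm, which oxidises medium-chain fatty acids, at -0.94. That call was lost without WT replicate 4 or control antibody replicate 1 (camera adjusted p = 0.0872 and 0.123) and with the replicate block (camera adjusted p = 0.0962). The oxidative stress list was called for anti-C5 against control antibody, with 8 of 20 lower and 1 higher (10 and 4 adjusted over the list alone; camera adjusted p = 0.0135; adjusted p = 0.399 with an estimated correlation), lost without control antibody replicate 3 (camera adjusted p = 0.0723) and with the run as a term (camera adjusted p = 0.0633). The perirenal fat list lay lower in anti-C5 than in WT kidneys, with a median of -1.30 over 8 members, 0 called by edgeR (0 higher and 2 lower adjusted over the list alone; 6 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom), a camera adjusted p of 9.54e-05 and adjusted p = 0.57 with an estimated correlation. Also lower there by camera were proximal tubule, fatty acid oxidation and oxidative phosphorylation genes (adjusted p = 0.0188, 0.0445 and 4.1e-07; adjusted p = 0.815, adjusted p = 0.839 and adjusted p = 0.57 with an estimated correlation), and higher were mesangial and immediate early and heat shock genes (adjusted p = 0.006 and 0.000346; adjusted p = 0.57 with an estimated correlation for both). Of these, the proximal tubule call was lost without anti-C5 replicate 1 (camera adjusted p = 0.0811), that of fatty acid oxidation without WT replicate 3 or 4 or anti-C5 replicate 2 or 3 (camera adjusted p = 0.0825 to 0.354) and the mesangial call without anti-C5 replicate 4 (camera adjusted p = 0.0598). Of the adrenal gland list 1 member was measured in experiment 2 and 2 in experiment 3. Both cold-inducible genes, Cirbp and Rbm3, were higher in huC3 than in WT in experiment 2 (0.96 and 1.28) and with control antibody (1.73 and 0.98), and lower with anti-C5 than with control antibody (-1.82 and -0.83). In experiment 2 the call of Cirbp was lost without WT replicate 1, 2 or 3 (adjusted p = 0.0607 to 0.104), and that of Rbm3 with anti-C5 was lost without control antibody replicate 1 or 3 or anti-C5 replicate 1, 2 or 3 (adjusted p = 0.0511 to 0.119). Liver transcripts were called lower for 4 of 31 and higher for 0 with anti-C5 against control antibody (camera adjusted p = 0.0105; adjusted p = 0.488 with an estimated correlation), with the highest values in the library labelled huC3 control antibody replicate 1. They also lay lower with anti-C5 than in WT, with a median of -1.26 (camera adjusted p = 5.85e-07; adjusted p = 0.275 with an estimated correlation). All 5 WT libraries of experiment 3 held 9.89 to 14.9 CPM of 7 liver-restricted transcripts in sum, against 0 to 0.362 CPM in 5 of the 7 huC3 libraries and 14.8 and 87.3 CPM in anti-C5 and control antibody replicate 1. Every library at 9.89 CPM or more belonged to the WT run, where anti-C5 replicate 2 held 0.222 CPM. No library of the huC3-only run held more than 0.362 CPM. Genotype and treatment differences in liver transcripts therefore cannot be told apart from the run.

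Within the huC3 kidneys of experiment 2, the 3 animals collected 14 to 27 days before the WT animals differed from the 3 collected on the WT day. Of the genes tested, edgeR called 1394, 448 higher and 946 lower in the earlier animals. Proximal tubule genes were lower for 16 of 28 members, with a median of -0.738 (camera adjusted p = 4.9e-21; adjusted p = 0.282 with an estimated correlation), and oxidative phosphorylation genes were lower for 18 of 22. Kap lay at a log2 fold change of -1.78 ± 0.43 (SE, adjusted p = 0.0351). Age and collection day cannot be separated in these 6 animals, while 2 of their 3 birth dates held animals of both sets.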
